A study of Bactrocera dorsalis with 3 samples.

How the data were processed

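RNA was taken from Bactrocera dorsalis embryos of 3 ages after egg laying (0-1 hpo, 2-4 hpo and 5-8 hpo, where hpo stands for hours post-oviposition), with 1 library per age. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was selected on poly-T beads, and complementary DNA was primed with random hexamers for Illumina sequencing. Per the submitters' processing notes, HISAT2 2.0.4, a read aligner, and HTSeq 0.9.1, a read counter, were used. The role of each, their settings, the strand setting, the genome build and the annotation are not given in the sources used here. Poly-T selection makes each value depend on the poly-A tail as well as on the amount of RNA, which matters in early embryos, where tail length can change without transcription.

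The deposited files were 1 table of FPKM values for 13489 genes in the 3 libraries and 3 tables of read counts per gene with scaffold, strand, start, end and exonic length. The deposited FPKM values (named so per the file headers; fragments scaled to transcript length and library total) were set against the counts, which gives the length behind each value. These lengths were identical between libraries, but differed by over 0.1% from the listed length for 2742 of 11848 genes with an FPKM above 0, 23.1%, tra-2 among them. For these genes FPKM cannot be recomputed with the listed length, and implied lengths ranged from 0.323 to 1.67 times the listed ones. Ratios between ages are not affected by this, while levels of those genes depend on the length used. The deposited counts were whole numbers and were used for read totals, counting intervals and floors, with no normalization beyond the total. Models whose span equals the listed exonic length were called single-exon. No per-sample column was left out.

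Gene names came from a table of RefSeq genes of assembly ASM2337382v1, which may differ from the build used by the authors, so only names and gene types were taken from it. Of 13489 identifiers, 11887 matched. Of the rest, 371 were models without a gene number and 1231 were numbered genes. An informative name was found for 76 genes, 57 by symbol and 19 by synonym only. All other genes are known here by identifier alone.

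Comparisons used log2(FPKM + 1), which understates the change of low genes, over genes with FPKM of 1 or more in either library of the pair. Genes at least 4-fold higher or lower were counted. Counts of genes past a fold and the classes use FPKM + 1 throughout. Folds printed for single genes are ratios of FPKM without the pseudocount, with the exact conditional binomial interval of the 2 counts. Where a library had 0 reads, the fold is a lower bound against 3 reads in that library. As each age had 1 library, no p-value across genes was computed, and rules of size chose what is reported. These rules, the classes, the gene lists and most alternatives were fixed before the data were examined. The named genes are, in each comparison, the 10 largest rises and 10 largest falls on log2(FPKM + 1) among named genes with FPKM of 10 or more in either library, with 5 to 10 of each printed. To these were added up to 4 members of each gene list with FPKM of 5 or more, the sex determination genes, and the 5 most abundant named genes of each library. Single members of lists below FPKM 5, the named genes 41, Ygd6, Mfd6a, CP391 and EST3A, and the 4 genes known by identifier alone were added after their values were seen.

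The 22 gene lists covered processes of early fly development, and 17 had no gene that could be matched by name. Matched were the lists for sex determination, small RNA machinery, heat shock, eggshell and yolk, and late embryo and adult tissue. Medians of the heat shock list were set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Structure of the onset classes was set against lists matched on FPKM at 2-4 hpo for early onset, at 5-8 hpo for late onset and at 0-1 hpo for the steep fall. Adjacent pairs of early-onset genes were counted along scaffolds and set against 10000 random draws.

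Alternatives were a pseudocount of 0.1, other thresholds for detection and for the classes, no filter on low values, the TPM scale, median-of-ratios scaling, values recomputed from the counts, and RPM (reads scaled to the library total without a length term). The procedures were tested on simulated counts for 13489 genes with 200 genes changed. These counts held counting noise only, around means pooled over the 3 libraries. Changed genes and checked intervals were limited to genes with at least 200 reads expected in the smallest library. The simulation therefore says nothing of false calls from differences between libraries or embryos, or of genes with few reads. For 8-fold changes at 2-4 against 0-1 hpo, 100% of raised and 86% of lowered genes were called at 4-fold, with 0 unchanged genes called, and 95.2% of the 95% intervals held the true ratio. For 8-fold changes at 5-8 against 2-4 hpo 99% and 85% were called, and at 5-8 against 0-1 hpo 100% and 90%. Analyses used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.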

Results

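The data are RNA-seq profiles of early embryos of the oriental fruit fly, Bactrocera dorsalis, collected at 3 ages after egg laying: 0-1, 2-4 and 5-8 hours post-oviposition (hpo). Each age was represented by 1 library, so no difference between ages has a replicate check and no p-value is given. Reads assigned to genes numbered 68140879 at 0-1 hpo, 65069185 at 2-4 hpo and 74817640 at 5-8 hpo, over 13489 gene models. At these depths a gene with 0 reads could still have stood at up to 0.0440, 0.0461 and 0.0401 RPM (reads scaled to the library total) in the 3 libraries, the value of 3 reads. Intervals given with fold differences are 95% exact intervals from the read counts, and they and the floors cover counting error only. Positions are those in the deposited tables, whose genome build is not given in the sources used here.

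The number of detected genes depended on age and on the threshold. At an FPKM of 1 or more there were 7046 genes at 0-1 hpo, 7114 at 2-4 hpo and 7773 at 5-8 hpo, and genes with at least 1 read numbered 9540, 10575 and 11356. At higher thresholds the order changed: 6340, 5876 and 6394 genes reached an FPKM of 5, and 5800, 5039 and 5427 reached 10. Protein-coding genes made up 6552, 6585 and 7082 of the genes at FPKM 1 or more, and long noncoding RNA genes 27, 31 and 44. The median FPKM of these detected genes was 32.8, 23.4 and 21.4. Across the 8230 genes detected in any library, Spearman's rho between libraries was 0.878 for 2-4 against 0-1 hpo and 0.709 for 5-8 against 2-4 hpo. It was 0.673 for 5-8 against 0-1 hpo; these are correlations across genes, which are not independent replicates.

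Among the 76 genes with an informative name, transcripts encoded by the mitochondrial genome were the most abundant in each library. At 0-1 hpo these were ATP6 (FPKM 3183), COX3 (2592), COX1 (2084), COX2 (1287) and ND3 (749), which encode subunits of the ATP synthase and the respiratory chain. At 2-4 hpo they were ATP6 (5788), COX3 (4746), COX1 (4378), COX2 (2246) and CYTB (1171). At 5-8 hpo COX3 (5725) and COX1 (5277) stood above ATP6 (4608), COX2 (2615) and CYTB (1487). Mitochondrially encoded genes took 1.04% of reads at 0-1 hpo, 1.96% at 2-4 hpo and 2.18% at 5-8 hpo.

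The first comparison asked which transcripts differed between newly laid eggs and embryos of 2-4 hpo, and most large differences were losses. The largest among named genes was that of DNAJ1, an Hsp40-type co-chaperone, at FPKM 323 at 0-1 hpo and 25.1 at 2-4 hpo, 12.9-fold lower (12.4 to 13.4). CH60, the mitochondrial chaperonin Hsp60, was 7.15-fold lower (6.93 to 7.38), from 257 to 35.9. The copper-zinc superoxide dismutase gene SODC was 6.10-fold lower (5.86 to 6.35), and the small GTPase gene Rab40 was 5.15-fold lower (4.89 to 5.43). The cytochrome P450 gene CYP6G6v2 went from 377 to 76.4, 4.93-fold lower (4.83 to 5.05).

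DNAJ1 lies on scaffold NW_011876154.1, minus strand, positions 174936 to 177464, and CH60 on NW_011876229.1, minus strand, 328786 to 330740. SODC lies on NW_011876380.1, minus strand, 2037028 to 2038516. Smaller losses at 2-4 hpo were seen for Zn-CuSOD, a second copper-zinc superoxide dismutase gene (3.44-fold), E4f1 (3.00-fold), Adf1 (2.86-fold), Rab5b (2.68-fold) and L12r1 (2.59-fold). No named gene was at least 4-fold higher at 2-4 hpo on the log2(FPKM + 1) scale. Among named genes with FPKM of 10 or more at either age, the largest gain was that of Zn800, from FPKM 126 to 394, 3.12-fold (3.08 to 3.16). It was followed by ND4 (2.59-fold), COX1 (2.10-fold), CYTB (2.06-fold) and ND5 (2.00-fold), all encoded by the mitochondrial genome.

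Of the 7310 genes with an FPKM of 1 or more in either library, 126 were at least 4-fold higher and 605 at least 4-fold lower at 2-4 hpo. At 2-fold the numbers were 406 and 1721, and 5183 genes differed by less. The 605 lower genes had median FPKM values of 38.0, 5.44 and 15.8 at the 3 ages. Of them, 223 were at least 4-fold higher again at 5-8 hpo than at 2-4 hpo, CH60 the only named gene among these. At 5-8 hpo 275 of the 605 were within 2-fold of their level at 0-1 hpo, and 187 were still at least 4-fold below it. The 126 higher genes had medians of 0.0531, 23.3 and 36.9, and 93 of them were still at least 4-fold above the 0-1 hpo level at 5-8 hpo. With a pseudocount of 0.1 in place of 1, the counts were 207 higher and 766 lower genes.

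**Figure D1:**
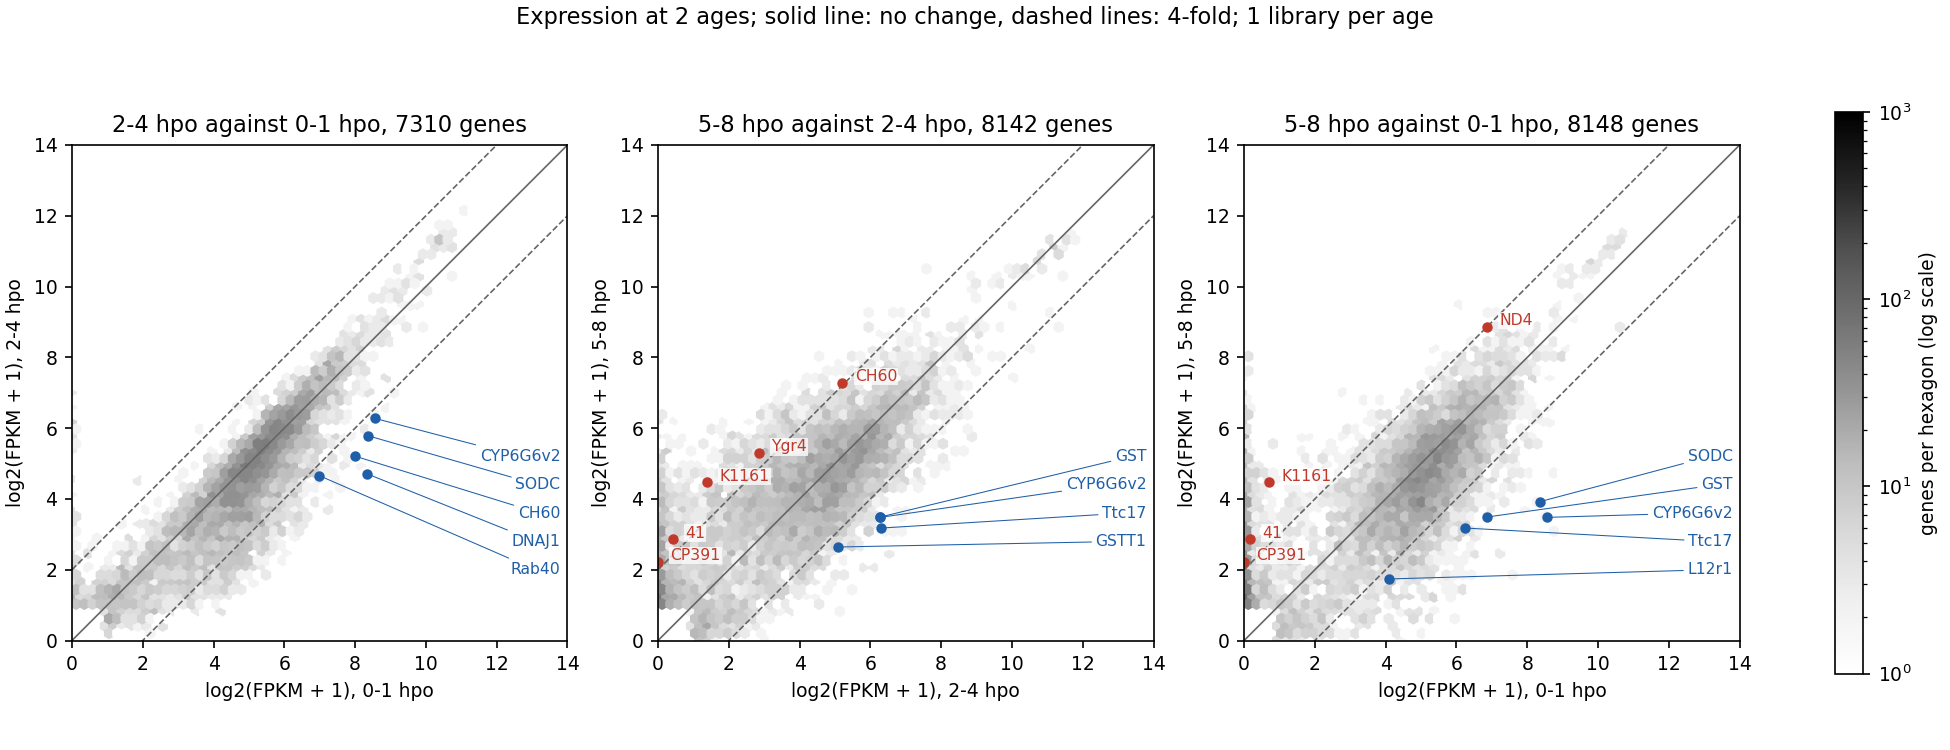
Each panel plots log2(FPKM + 1) of genes at 2 ages against each other, with grey hexagons shaded by the number of genes. The solid line marks equal values, dashed lines 4-fold differences, and labelled points are the named genes at least 4-fold higher (red) or lower (blue) at the later age. At 2-4 hpo 605 genes lay below the lower dashed line and 126 above the upper one, and at 5-8 hpo against 2-4 hpo the numbers were 513 and 1121.

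Between 2-4 and 5-8 hpo gains outnumbered losses. Among named genes with FPKM of 10 or more at either age, K1161 was 13.1-fold higher at 5-8 hpo (11.8 to 14.5), from FPKM 1.61 to 21.1, and Ygr4 was 6.18-fold higher (5.56 to 6.89). CH60 was 4.33-fold higher (4.19 to 4.47) and DNAJ1 3.29-fold higher (3.16 to 3.42), so both chaperone genes had their lowest value at 2-4 hpo. Rab5b, a GTPase of early endosomes, was 3.81-fold higher (3.65 to 3.96), Rab1a, a GTPase of transport from the endoplasmic reticulum, 3.26-fold (3.22 to 3.31), and the protein kinase gene Akt1 3.07-fold (3.00 to 3.13).

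Losses at 5-8 hpo included CYP6G6v2 and the glutathione transferase genes GST and GSTT1. CYP6G6v2 was 7.53-fold lower than at 2-4 hpo (7.12 to 7.97), and GST and GSTT1 were 7.46-fold (6.93 to 8.03) and 6.29-fold (5.61 to 7.08) lower. NCPR, which encodes the reductase that passes electrons to cytochrome P450 enzymes, was 2.93-fold lower, from FPKM 311 to 106. The largest loss among named genes with FPKM of 10 or more was that of Ttc17, 9.70-fold (9.19 to 10.2), from 78.0 to 8.05. SODC was 3.81-fold lower, Irs1, which encodes an insulin receptor substrate, 3.73-fold, Ngrn 3.47-fold, Csga 3.03-fold and Zn800 2.72-fold. CP391, which had 0 reads at 0-1 and 2-4 hpo, had 782 reads at 5-8 hpo (FPKM 3.67), at least 227-fold higher than at 2-4 hpo. K1161 lies on NW_011876368.1, minus strand, 718981 to 733248, and Ttc17 on NW_011876253.1, plus strand, 234122 to 237023.

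Of 8142 genes compared between 2-4 and 5-8 hpo, 1121 were at least 4-fold higher and 513 at least 4-fold lower. At 2-fold the counts were 2471 and 1719. Higher genes made up 68.6% of the 4-fold differences here against 17.2% between 0-1 and 2-4 hpo. With a pseudocount of 0.1 the counts were 1616 higher and 783 lower genes.

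Named genes differed in both directions between 0-1 and 5-8 hpo. CYP6G6v2 was 37.2-fold lower (35.2 to 39.2), from FPKM 377 to 10.2, and SODC was 23.2-fold lower (21.7 to 24.9), from 330 to 14.2. GST was 11.2-fold lower (10.4 to 12.1), Ttc17 9.35-fold (8.86 to 9.87) and L12r1 6.87-fold (6.08 to 7.78). DNAJ1 remained 3.92-fold below its 0-1 hpo level. E4f1 (4.38-fold), GSTT1 (4.09-fold), So5a1 (3.81-fold) and Zn-CuSOD (3.75-fold) were also lower.

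Among named genes with FPKM of 10 or more at either age, K1161 showed the largest gain from 0-1 to 5-8 hpo, 33.4-fold (28.6 to 39.3), from FPKM 0.632 to 21.1. Larger folds were found among named genes below that level, chosen after their values were seen. The gene listed as 41 was 53.2-fold higher (40.2 to 71.9), Ygd6 48.7-fold (24.5 to 114), Mfd6a at least 168-fold and CP391 at least 237-fold. ND4 was 4.03-fold higher (3.94 to 4.11) and Rab1a 3.66-fold (3.60 to 3.71), Rab1a reaching FPKM 683. CYTB (2.62-fold), COX1 (2.53-fold), Ygr4 (2.39-fold), T53i1 (2.34-fold), ND2 (2.23-fold), ND5 (2.23-fold) and COX3 (2.21-fold) followed. CYP6G6v2 lies on NW_011876177.1, minus strand, 11120 to 15825, and Rab1a on NW_011876264.1, plus strand, 36839 to 40579.

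Larger differences were found among genes without an informative name. LOC105223182 on NW_011876267.1, plus strand, 415874 to 416595, had 84557 reads at 0-1 hpo and 320 at 5-8 hpo, 290-fold lower (260 to 325). LOC105232175 on NW_011876398.1, minus strand, 4772378 to 4773075, was 280-fold lower (246 to 321). LOC105225818 on NW_011876334.1, minus strand, 285698 to 286647, had 0 reads at 0-1 hpo, 575 at 2-4 hpo and 70961 at 5-8 hpo. Taking 3 reads for the 0, its level at 5-8 hpo was at least 21543-fold higher than at 0-1 hpo. LOC105227214 on NW_011875868.1, minus strand, 38910 to 39564, went from 0 reads to 77 and 47579, at least 14444-fold higher.

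Across the whole interval 879 of 8148 genes were at least 4-fold higher and 844 at least 4-fold lower at 5-8 hpo. At 2-fold there were 1940 higher and 2215 lower genes. With a pseudocount of 0.1, 1347 genes were at least 4-fold higher and 1098 at least 4-fold lower. After median-of-ratios scaling the 4-fold counts were 943 higher and 736 lower genes. On the TPM scale the order was reversed, with 1011 higher and 1061 lower, so the balance over the whole interval depended on scaling. Genes above FPKM 1 in all libraries had a median log2 ratio below 0 in each comparison: -0.23 for 2-4 against 0-1 hpo, -0.07 for 5-8 against 2-4 hpo and -0.37 for 5-8 against 0-1 hpo. Over all genes compared, the medians on log2(FPKM + 1) were -0.21, 0.11 and -0.17, so the second had the opposite sign. For genes above FPKM 1 in all libraries, after median-of-ratios scaling the medians were -0.03, -0.11 and -0.20, and on the TPM scale they were -0.33, -0.12 and -0.51. Against the shift of -0.37, the log2(FPKM + 1) ratio was 2.00 for ND4 and -5.08 for CYP6G6v2.

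**Figure D2:**
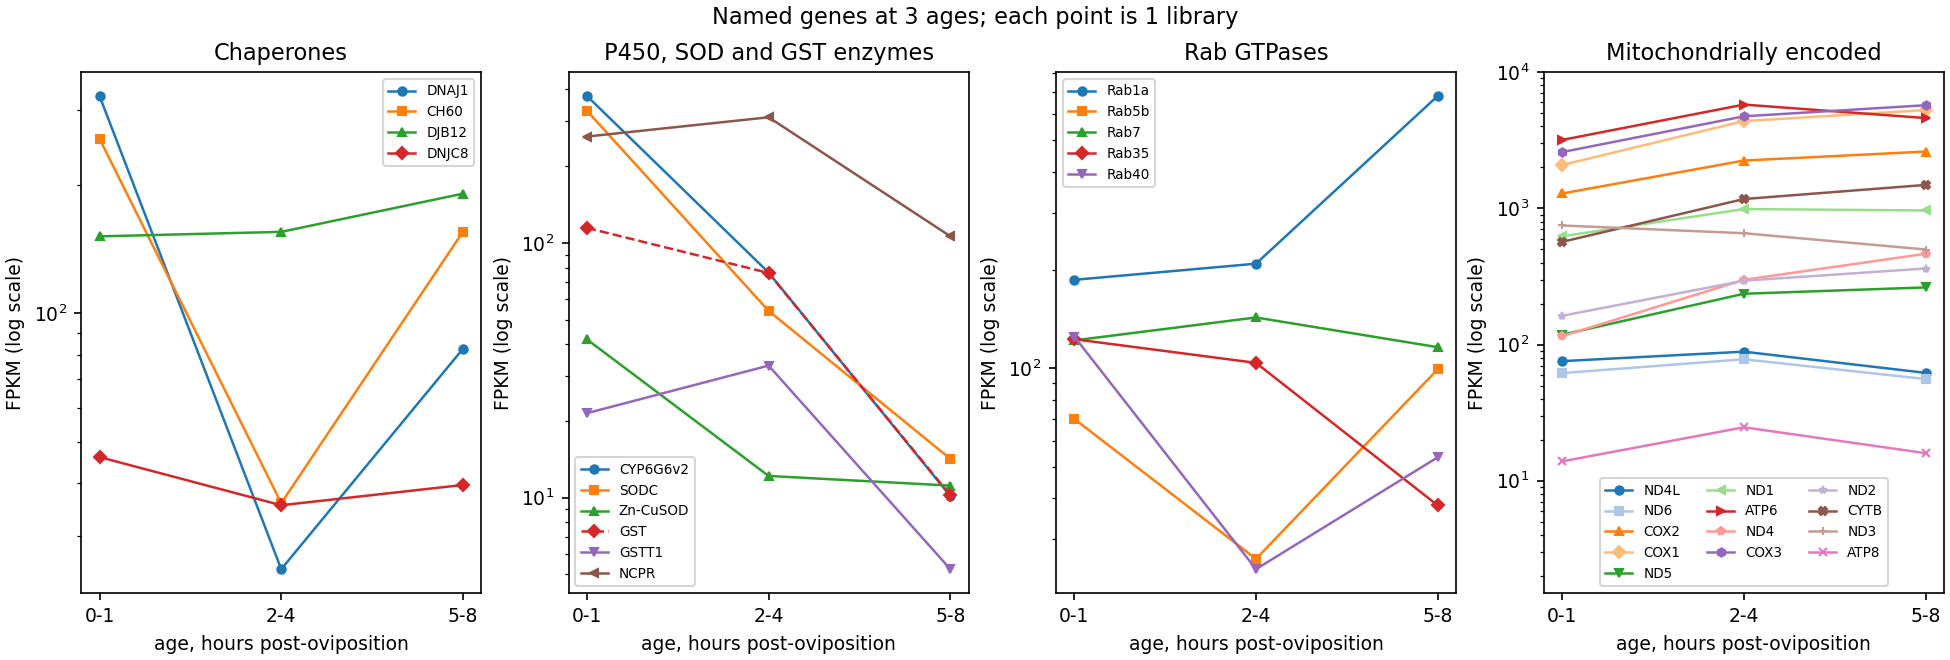
FPKM on a log scale (y) at the 3 ages in hours post-oviposition (x) for named genes in 4 groups, each point 1 library. DNAJ1 and CH60 had their lowest values at 2-4 hpo, 25.1 and 35.9, as did Rab5b and Rab40, 26.1 and 24.3. CYP6G6v2, SODC and GST had theirs at 5-8 hpo, 10.2, 14.2 and 10.2. The enzyme panel shows 6 genes chosen after their values were seen. It leaves out CP391 and EST3A, which are grouped with them in a later passage and were higher at 5-8 than at 0-1 hpo. Rab1a reached 683 at 5-8 hpo, and ND3 was the mitochondrial gene with the lowest ratio of 5-8 to 0-1 hpo, 0.666.

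Genes were also classed by their course over the 3 ages, with folds taken on FPKM + 1. Early onset, below FPKM 1 at 0-1 hpo and at 5 or more at 2-4 hpo, was met by 72 genes, with median FPKM 0, 25.9 and 27.5. Late onset, below FPKM 1 at both earlier ages and at 5 or more at 5-8 hpo, was met by 373 genes (212 with FPKM 10 in place of 5), with medians 0.0106, 0.144 and 12.1 for the 373. The late-onset class held 1 named gene, listed under the symbol 41, at FPKM 0.118, 0.337 and 6.26. A steep fall, from FPKM 10 or more at 0-1 hpo to at least 10-fold less at 5-8 hpo, was met by 239 genes, CYP6G6v2, SODC and GST among them, with medians 76.4, 23.1 and 2.76. A peak at 2-4 hpo, at least 4-fold above both other ages, was met by 24 genes, 13 of them models without a gene number, with medians 0, 59.2 and 0.586. None of the early-onset or peak genes had an informative name. The stable class, with less than 2-fold between any pair of ages on FPKM + 1, held 2671 genes, 24 of them named, including tra-2, Rab7 and TREA, which encodes trehalase.

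The classes differed in gene structure. Single-exon models, whose exonic length equals their span, made up 28 of the 72 early-onset genes, 38.9%, against 8.32% of all 8230 detected genes. Random lists of 72 genes matched on FPKM at 2-4 hpo held a median of 6.94% (central 95%, 2.78 to 13.9). Late-onset genes were single-exon in 14.5% of cases, against 8.04% in matched lists (5.63 to 10.7), and 24 of the 239 steep-fall genes were single-exon, against 7.53% in matched lists (4.60 to 10.9). Early-onset genes were also compact, with a median span of 1606.5 bases against 2899 in matched lists. Late-onset genes had a median span of 6002 bases against 3202, and steep-fall genes 4655 against 2646.

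**Figure D3:**
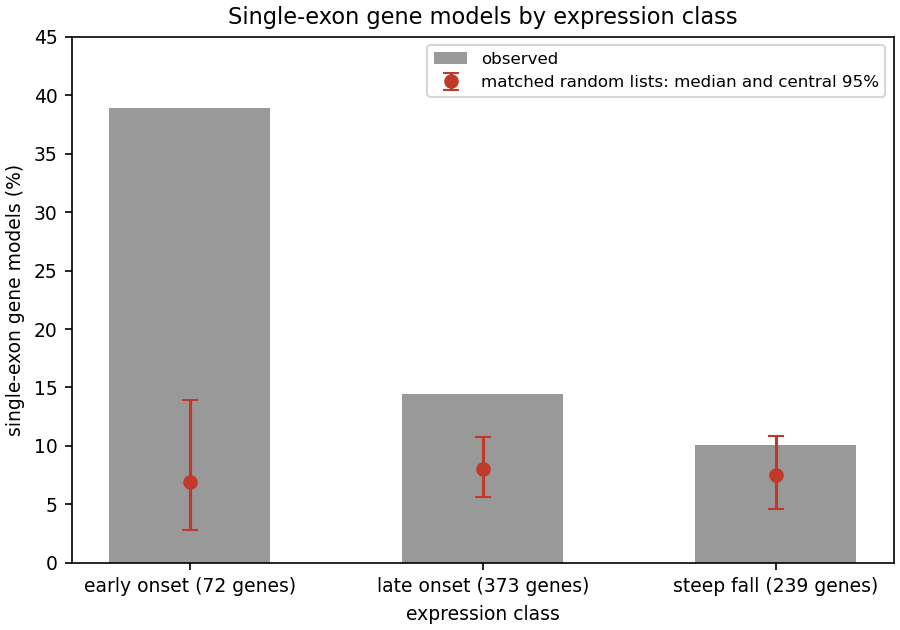
Bars give the percentage of single-exon gene models (y, from 0) in 3 expression classes (x). Red points and whiskers give the median and central 95% of 10000 random gene lists matched on expression at the age that defines the class. Early-onset genes, at 38.9%, lay above the range of 2.78 to 13.9, late-onset genes, at 14.5%, above 5.63 to 10.7, and steep-fall genes within 4.60 to 10.9.

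Some early-onset genes lay side by side. The 72 genes included 16 in 4 runs of neighbouring models, and these runs were chosen after their values were seen. The longest was 8 consecutive early-onset models on NW_011876205.1, positions 381846 to 438011, 7 of them single-exon and 5 without a gene number. Their reads numbered 0 to 2 at 0-1 hpo and 1085 to 13707 at 2-4 hpo, and their FPKM at 5-8 hpo ranged from 0.350 to 167. Another run of 4 models on NW_011876086.1, positions 1626 to 29160, had 0 reads at 0-1 hpo, FPKM 7.70 to 99.5 at 2-4 hpo and 0.0106 to 1.79 at 5-8 hpo.

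**Figure D4:**
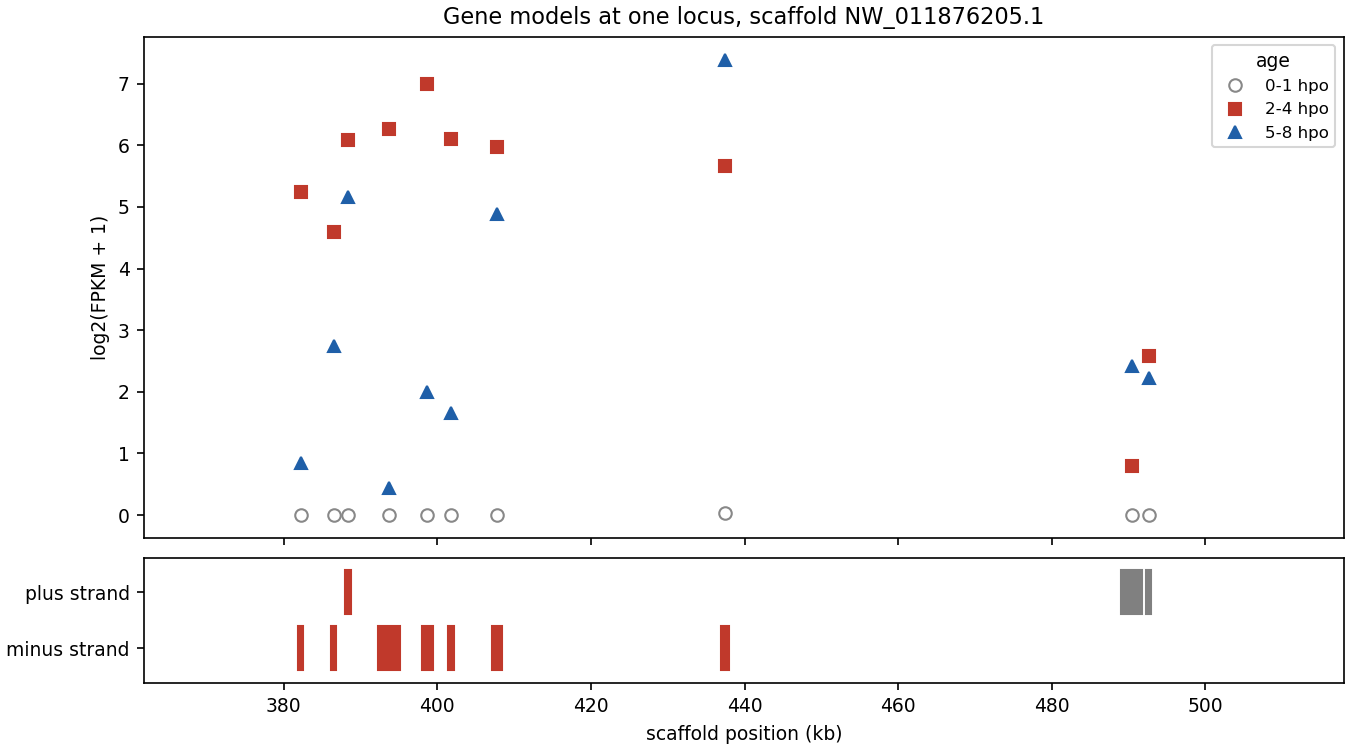
The upper panel gives log2(FPKM + 1) (y) of each gene model on part of scaffold NW_011876205.1 at the 3 ages, against position in kilobases (x). The lower panel draws the models to scale by strand, early-onset models in red and others in grey. The 8 early-onset models between 381846 and 438011 had 0 to 2 reads at 0-1 hpo (open circles) and FPKM 23.3 to 127 at 2-4 hpo (squares).

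Of 22 gene lists written for early fly development, 5 held any gene that could be matched by name, 8 genes in all. The heat shock list held DNAJ1, CH60, DJB12 and DNJC8. At 2-4 hpo DNAJ1 and CH60 were more than 2-fold lower, while DJB12 (FPKM 152 and 155) and DNJC8 (46.0 and 35.5) differed by less. The list's median log2 ratio, -1.59, lay at percentile 0.41 of matched random lists (central 95%, -0.99 to 0.63). At 5-8 against 2-4 hpo DNAJ1 and CH60 were more than 2-fold higher, and the median of 0.99 lay at percentile 94.2. At 5-8 against 0-1 hpo only DNAJ1 of the 4 differed by over 2-fold, and the median of -0.47 lay at percentile 30.2.

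The other matched lists each held 1 gene, so only its values are given. The sex determination list was represented by tra-2, a splicing regulator, on NW_011876234.1, plus strand, 178320 to 181657. Its FPKM was 97.1 at 0-1 hpo, 122 at 2-4 hpo and 91.9 at 5-8 hpo. From the list of small RNA machinery, Prkra, whose synonym in the reference table is R2D2, stood at 38.9, 30.0 and 45.8. From the eggshell and yolk list, VIT1, a yolk protein gene, stood at 1.58, 3.02 and 1.13. Rh1, an opsin gene from the list of late and adult tissues, had 0 reads in all 3 libraries.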

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

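Alternatives that could move a count gave 64 values for 14 counts of genes, and 59 were within 1.5 times the reported count. Among these, a filter at FPKM 5 and values recomputed from the counts had little room to move the 4-fold counts. A 4-fold call on FPKM + 1 already leaves out the lowest genes, and length nearly cancels in a ratio. For genes lower at 2-4 than at 0-1 hpo they gave 600 and 603 in place of 605. Counts within 1.5 times can still change order: at 5-8 against 0-1 hpo the TPM scale gave 1011 higher and 1061 lower genes, in place of 879 and 844. Another 12 values, without the filter on low values or with thresholds that a class does not use, were fixed by construction and say nothing of stability. The 24 values for the heat shock list count 0 to 2 of its 4 genes and equalled the reported ones. With a pseudocount of 0.1, 207 in place of 126 genes were higher at 2-4 than at 0-1 hpo, 783 in place of 513 were lower at 5-8 than at 2-4 hpo, and 1347 in place of 879 were higher at 5-8 than at 0-1 hpo, since a smaller pseudocount lets genes of lower FPKM reach 4-fold. With an on threshold of FPKM 10, 212 in place of 373 genes had late onset, by the construction of a stricter threshold. Without models that carry no gene number, an alternative added after seeing the data together with thresholds on RPM, 11 in place of 24 genes peaked at 2-4 hpo, because 13 of the 24 were such models. No paired analysis was possible because each age had 1 library. Depth limits statements on genes without reads to about 0.0401 to 0.0461 RPM.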

Other observations

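The 3 groups of named genes described first were put together after their values were seen, so they are given as values with no test. The tests for divided transcripts and for the scaling of the 2-4 hpo library were also chosen after the result was seen. Thresholds on RPM and the removal of models without a gene number were added after seeing the data, before their own results were known.

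The 13 protein-coding genes of the mitochondrial genome did not move as a block. At 2-4 against 0-1 hpo 12 of the 13 were higher and only ND3 was lower. Their median log2 ratio was 0.85, with 3 members at least 2-fold higher (8 after median-of-ratios scaling and 1 on the TPM scale). At 5-8 against 0-1 hpo 7 were at least 2-fold higher, and the median was 1.02. ND4 stood 4.03-fold above its 0-1 hpo level, while ND3, ND4L and ND6 had ratios of 0.666, 0.820 and 0.905. ND3, ND4L and ND6 are short, at 352, 297 and 524 bases, and ATP8, at 162 bases, had a ratio of 1.15. All members of 677 bases or more had ratios from 1.45 to 4.03. The split thus followed gene length, and whether length itself is the cause was not tested. ND4 and ND4L also overlap by position on the minus strand. After median-of-ratios scaling ND3 and ND4L stayed below 1, at 0.748 and 0.922, and ND6 moved to 1.02.

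A second group was put together from the symbols of 8 named genes: CYP6G6v2, CP391, SODC, Zn-CuSOD, GST, GSTT1, NCPR and EST3A. Of the 7 detected at any age, 3 were at least 2-fold lower at 2-4 than at 0-1 hpo (CYP6G6v2, SODC and Zn-CuSOD). GSTT1 (FPKM 21.5 and 33.0) and NCPR (261 and 311) were higher. The median log2 ratio over the 7 was -0.58. It counts CP391, without reads at both ages, as 0, and would be lower without that gene. At 5-8 against 2-4 hpo 5 were at least 2-fold lower and CP391 was higher. At 5-8 against 0-1 hpo CYP6G6v2, SODC, GST, GSTT1, Zn-CuSOD and NCPR were at least 2-fold lower, with a group median of -1.85. CP391 went from 0 reads at 0-1 and 2-4 hpo to 782 at 5-8 hpo, and EST3A stayed below FPKM 1. The Rab GTPase genes took separate courses: Rab1a was 3.66-fold higher at 5-8 than at 0-1 hpo, Rab7 stood at FPKM 122, 143 and 116, Rab35 went from 123 to 38.1, and Rab40 from 125 to 24.3 and 53.5.

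Early-onset genes held single-exon models in 38.9% of 72 cases, above matched random lists. These lists draw genes singly, while some of the 72 lie side by side. The run of 8 neighbours on NW_011876205.1 held 7 single-exon models, and the run of 4 on NW_011876086.1 held 2. The excess thus rests in part on few loci, and genes outside the runs were not compared separately. A candidate technical source is the length term of FPKM, which lets a short model pass a threshold with fewer reads. With thresholds on RPM (reads scaled to the library total, with no length term), 82 genes met the definition and 34.1% were single-exon, against 2.44 to 13.4 in matched lists. Without the models that carry no gene number, 54 genes were left and 38.9% were single-exon, above a range of 1.85 to 14.8, so those models alone do not account for the excess. Preferential early transcription of genes without introns stays as a hypothesis, since a reference sequence to test for duplicated genes was not used here.

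Early-onset genes lay side by side more often than random draws did. The 72 genes formed 12 adjacent pairs, against a mean of 0.508 and a maximum of 5 in 10000 random draws of 72 genes expressed at 2-4 hpo. No pair overlapped, so all 12 were left without overlapping models. In 8 pairs the members' ratios of 5-8 to 2-4 hpo differed over 2-fold with separate intervals, which argues against 1 transcript divided into neighbouring models as the whole cause. As annotated, 6 of the 12 pairs lay on opposite strands, which 1 divided transcript would not give. Some of the 6 include models without a gene number, and how the strand of such models was set is not given in the sources used here. The opposite-strand pairs of numbered genes were LOC105232944 with LOC105232945, LOC105234275 with LOC105234276, and LOC105227161 with LOC105227162. Outside the longest run 5 pairs remained. When models without a gene number were removed before neighbours were counted, the 54 numbered genes formed 4 pairs. Random draws made the same way gave a mean of 0.300 and a maximum of 4. These pairs include LOC105234276 with LOC105234277, between which removed models lie. Reads shared between tandem copies stay open, as does shared regulation of neighbours, which is a hypothesis.

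At 2-4 hpo 223 genes stood at least 4-fold below both other ages, against 24 at least 4-fold above both. After median-of-ratios scaling 183 stood below and 26 above, so a low overall scaling of that library does not account for them. Loss of long transcripts would make these genes long, but their median exonic length of 1713 bases lay below the 1971 of matched lists. It also lay below the central range of those lists, 1753 to 2201, at percentile 0.965, so these genes were short. Whether short length is linked to the low values at 2-4 hpo was not tested and stays open. These genes had a median of 558 reads at 2-4 hpo. Few reads were therefore not typical of these genes. Simulations of unchanged libraries, with counting noise only, gave at most 0 such genes in 100 draws. Counting noise at such read numbers could hardly give a 4-fold drop below both other ages. The outcome of the simulations was thus all but fixed beforehand, and no conclusion on the cause is drawn from them. The simulations also say nothing of other variation between libraries. A change in poly-A tail length seen through poly-T capture, an effect particular to the single 2-4 hpo library, and loss of maternal RNA followed by embryonic transcription were not tested and stay open.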
